A study of Marchantia polymorpha with 18 samples.

How the data were processed

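Messenger RNA was measured in thallus of the liverwort Marchantia polymorpha, the flat plant body that dominates its life cycle. Wild-type plants were compared with Mpglr-9, a deletion mutant made by CRISPR editing of MpGLR, the gene of a glutamate receptor-like protein. Plants had grown on soil for 28 days. On wounded plants 2 lobes were crushed with serrated forceps, and the crushed lobes (damaged) and the adjacent untouched lobes of the same plants (systemic) were taken separately after 4 h, together with thallus of unwounded plants (intact). Each of the 6 groups held 3 biological replicates, each pooled from 9 plants, which makes 18 libraries. The crushed and untouched lobes came from the same wounded plants, but the labels do not tie a damaged library to a systemic one beyond the shared replicate number.

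Per the labels' protocols, the libraries were made from poly-A selected RNA with the NEBNext Ultra RNA kit and sequenced as paired reads of 150 bases on a NovaSeq instrument. Per the submitters' processing notes, the authors used HISAT2 for alignment and HTSeq for counting; versions, options, the strand setting and the genome build are not given in the sources used here. The authors deposited the values as raw read counts per gene, in 1 table of 19355 genes and 18 libraries with 3 empty columns at its end. The strand setting decides how reads of overlapping genes on opposite strands are assigned, and genes with near-identical copies may share or lose reads, which matters most for the large tandem families named in the report. The totals ran from 17312755 to 30690205 counts per library, so that 3 counts, the limit taken for a gene with no read, corresponded to between 0.098 and 0.173 CPM (counts scaled to a common library size). Such limits cover counting error only.

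Gene names came from the gene table of assembly MpTak2_v7.1. Its locus tags carry the same locus numbers as the deposited identifiers, and 17384 of the 19355 identifiers (89.8%) had a locus tag of the same number. These held 99.1% of all counts. A symbol was given for 3091 of the identifiers, which held 19.1% of the counts. Within each of 8 chromosomes the identifier number and the position in the table had a Spearman correlation of at least 0.9995 across genes. Because the authors' build is not stated, no coordinate was used, and the order of locus numbers served only to say which genes neighbour each other. No symbol of MpGLR is in the names used and no sequence was searched, so the targeted gene was not analysed here, and its expression gave no check of the genotype labels.

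The deposited counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with filterByExpr by group, which left 13450 genes. Library sizes were scaled with TMM, and a quasi-likelihood negative binomial model with robust dispersion and 6 group means was fitted to all 18 libraries, since 3 libraries per group give few degrees of freedom. Contrasts were tested with glmQLFTest, two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05. The comparisons were damaged against intact and systemic against intact in each genotype, mutant against wild type in each condition, and the interactions, that is the difference between the genotypes in the change from intact to damaged or from intact to systemic. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD of 3 libraries. Intervals of a log2 fold change are 95% intervals, the estimate plus and minus 1.96 standard errors.

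Gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. The lists were written as keywords for families and processes, and were translated into patterns of gene symbols when the names table was at hand, before any test. At that point cupins were split from the pathogenesis-related proteins and a list of reproductive genes was added. A photosystem list had no named member, a list on rhizoids had 2 tested members, and lists of ribosomal proteins, of organelle genes and of the U chromosome were not used here. The other 29 lists had at least 3 tested members. Each was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. The camera test compares a list with the other genes, so a shift common to all genes does not enter it. Members called over all tested genes are given beside those called when p-values are adjusted over the list alone.

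The candidates for naming in the text were up to 4 called members of each list with the largest absolute log2 fold change, and the 8 higher and 8 lower called genes of each comparison with the largest absolute log2 fold change among those with a mean of at least 5 CPM in the higher group and no overlap of replicates. For each interaction, 6 genes per direction with the smallest p were candidates. At most 2 unnamed identifiers that rose and 2 that fell were printed under the second part of the rule. The report names some of these candidates. Candidates with 3 or fewer counts summed over a compared group were passed over and others were left out for length, both after their values were seen. Mp4g19430 and Mp4g19400 in the report were named outside this rule after their values were seen. So were genes of neighbouring runs and of a stretch on chromosome 5 in the closing part.

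The share of the damaged response carried by a library was the projection of its log2 CPM change from the intact mean of its genotype on the change from intact to damaged in the other genotype, over the genes called there, so that the score shares no library with its reference. An intact library was set against the other intact libraries of its genotype. Whether a replicate number marks a shared batch is not stated. Deviations from the group means were therefore correlated between libraries of the same number. All 3 correlations were above 0.1 for mutant against wild type in intact plants (0.31, 0.49 and 0.68) and in damaged lobes (0.25, 0.12 and 0.39), so the numbers were taken to pair the libraries there. In these comparisons the fit with the replicate number as a block is given beside the result where it moves the count. In each of the other comparisons of 2 groups at least 1 correlation was below 0.1. Their mean correlation was still higher for the same number (0.14 to 0.29) than for other numbers (-0.14 to -0.07). Pairing is therefore not excluded there.

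Before use, the procedure was tested on simulated data with the library sizes and dispersions of the real libraries and 1 mean per gene in all groups, apart from 200 genes changed in 1 group. For wild-type systemic against intact it recovered 68% of the genes changed 1.5-fold, 82% of those changed 2-fold and 92% of those changed 3-fold, and 6 of 171 calls were false. For the interaction in damaged lobes it recovered 50% of the genes changed 1.5-fold and 68% of those changed 2-fold, and 10 of 153 calls were false. The chi-square per gene between replicate libraries ran from 4.75 to 26.46, so no pair within a group differed as little as a library deposited a second time would. Pairs from different groups were not compared in this way.

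The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, library totals with no scaling factor, no low-count filter (at least 1 read), a stricter filter (at least 1 CPM in 6 libraries), the replicate block, a fit on the groups compared alone, leaving out each library in turn, an adjusted p under 0.01, and a call that also needs an absolute log2 fold change of 1. For the gene lists they were camera with an estimated correlation, camera with the replicate block, and fry. The fry test asks whether a list changed at all, not whether it changed more than other genes, so its counts are not comparable with those of camera. Leaving out all libraries numbered 3 was added after the data were examined.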

Results

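Gene expression was profiled by RNA sequencing in thallus of wild-type Marchantia polymorpha and of the deletion mutant Mpglr-9, to ask what the glutamate receptor-like gene MpGLR contributes to the changes that follow wounding. Thallus of intact plants, crushed lobes (damaged) and untouched lobes of the wounded plants (systemic) were collected 4 h after wounding, with 3 replicates in each of the 6 groups. Wild-type libraries held 22479343 to 30690205 counts in intact plants, 17312755 to 24209193 in damaged lobes and 18558026 to 28396396 in systemic lobes. Mutant libraries held 26861344 to 27856158 counts in intact plants, 21678546 to 22632143 in damaged lobes and 22027733 to 24647564 in systemic lobes. On the first principal component of log2 CPM, with 68.7% of the variance, all 6 damaged libraries lay between 56.4 and 81.1 and the other 12 between -38.3 and -29.7. The second component held 9.7% of the variance, and in each group the library numbered 3 had the highest value, reaching 36.9 in wild-type intact and 29.8 in mutant intact plants. Expression of MpGLR itself was not analysed here, because the names used pair no identifier with it.

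The comparison of damaged with intact wild-type thallus measured the local response to wounding. Crushing was followed by a change of 7469 of the 13450 tested genes, 3731 higher and 3738 lower, and 986 of the higher and 649 of the lower genes moved by at least 1 on the log2 scale. Genes of oxylipin synthesis, phenolic metabolism, dirigent proteins and WRKY transcription factors were among those that rose, while histone and cell-cycle genes and genes of chlorophyll synthesis were among those that fell. The polyphenol oxidase gene MpPPO31 rose from 0.609 ± 0.554 to 83.8 ± 16.9 CPM (SD, n = 3), a log2 fold change of 7.05 ± 0.46 (SE). Among genes without a symbol, Mp5g21760 rose from 5.21 ± 4.28 to 860 ± 198 CPM (SD, n = 3) and Mp7g12590 rose 156-fold, whereas Mp1g23830 fell by 2.68 and Mp4g19710 fell by 2.67 on the log2 scale. The split into higher and lower genes depended on the scaling, and directions are given relative to TMM. With upper-quartile scaling the median log2 fold change of all genes was -0.118, against -0.026 with TMM, and 37.8% of the calls were higher.

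Oxylipins are signals made from polyunsaturated fatty acids, and lipoxygenases catalyse their first step. Of 15 tested lipoxygenase genes 9 rose and 3 fell (9 and 4 adjusted over the list alone), and the list moved upward in the camera test (adjusted p = 0.0242), which did not hold with an estimated correlation (adjusted p = 0.559). MpLOX6 rose 93.2-fold and MpLOX8 rose 86.2-fold, both from low levels of 0.322 ± 0.157 and 1.58 ± 1.12 CPM in intact plants (SD, n = 3). MpLOX4 rose 48.4-fold, and the abundant MpLOX2 rose from 168 ± 25.2 to 1849 ± 242 CPM (SD, n = 3), a log2 fold change of 3.46 ± 0.11 (SE, adjusted p = 6.69e-13, edgeR quasi-likelihood test). In the list of later steps toward 12-oxo-phytodienoic acid and of fatty acid desaturases, 8 of 16 genes rose and 4 fell, the same counts as adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.124). The allene oxide synthase genes MpCYP74N2 and MpCYP74N1 rose 8.58-fold and 2.92-fold, and the desaturase gene MpFAD8 rose by 1.77 ± 0.19 on the log2 scale (SE). Of the 3 tested genes of jasmonate-type signalling, the repressor gene MpJAZ rose 5.12-fold (log2 fold change 2.36 ± 0.10, SE), MpCOI1, the gene of the oxylipin receptor, fell by 0.32 on the log2 scale, and MpNINJA, an adaptor of the repressor complex, rose by 0.16 ± 0.05. All 3 were also called when adjusted over the list alone, and the list did not pass (adjusted p = 0.416). The small change of MpNINJA was not called with upper-quartile scaling (0.07, adjusted p = 0.227), on the groups compared alone (0.17, adjusted p = 0.0772) or without damaged replicate 1 (0.11, adjusted p = 0.0742), and over all alternatives its adjusted p ran from 0.000668 to 0.227.

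At the entry to the phenylpropanoid pathway 12 of 16 genes rose and 1 fell (12 and 2 adjusted over the list alone), and the list passed camera (adjusted p = 0.000811) but not with an estimated correlation (adjusted p = 0.559). The 4-coumarate:CoA ligase gene Mp4CL2 rose from 146 ± 10.9 to 1363 ± 210 CPM (SD, n = 3), and the phenylalanine ammonia-lyase gene MpPAL4 rose 6.12-fold. In the chalcone synthase family and flavonoid synthesis 21 of 49 genes rose and 16 fell (21 and 17 adjusted over the list alone, camera adjusted p = 0.319). MpPKS/CHS21 rose 42.9-fold, and MpAUS, which encodes the enzyme of auronidin pigments, rose 23.5-fold. Of 36 polyphenol oxidase genes 12 rose and 4 fell (12 and 3 adjusted over the list alone, camera adjusted p = 0.0945), and MpPPO42 rose from 128 ± 48.0 to 3098 ± 437 CPM (SD, n = 3).

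Dirigent proteins, which steer the coupling of phenoxy radicals, made up the list with the smallest camera p. Of 47 dirigent genes 32 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.49e-07, and adjusted p = 0.559 with an estimated correlation). MpDIR61 and MpDIR39, which belong to a stretch of neighbouring dirigent genes, rose 107-fold and 92.5-fold, and reads shared between such copies could not be separated. Class III peroxidase genes moved the other way, with 41 of 102 lower and 9 higher (39 and 9 adjusted over the list alone, camera adjusted p = 0.00828, and adjusted p = 0.606 with an estimated correlation). MpPOD17 fell from 0.666 ± 0.324 CPM (SD, n = 3) to a level under the 0.124 to 0.173 CPM that a count of 0 allows in damaged lobes, while MpPOD161 rose 12.5-fold.

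Among transcription factor genes, 10 of 12 WRKY genes rose and none fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000391, and adjusted p = 0.559 with an estimated correlation). MpWRKY7 rose 27.6-fold from a low level and MpWRKY10 rose 3.16-fold. In the other 4 families the camera test did not pass, at adjusted p = 0.0741 for AP2/ERF and NAC, 0.319 for bHLH and 0.361 for MYB genes. Of 22 AP2/ERF genes 10 rose and 1 fell, of 8 NAC genes 6 rose and 1 fell, and of 46 MYB genes 14 rose and 9 fell, all unchanged when adjusted over the list alone. Of 37 bHLH genes 14 rose and 10 fell (15 and 10 adjusted over the list alone). Single members moved strongly. MpBHLH51 rose to 32.0 ± 18.7 CPM (SD, n = 3) from 0.128 ± 0.0864 CPM, near the limit of 0.098 to 0.133 CPM that a count of 0 allows in intact plants, so no fold is given. MpBHLH4 rose from 3.55 ± 1.92 to 363 ± 68.6 CPM (SD, n = 3), MpERF15 rose 12.7-fold, MpERF20 rose 9.33-fold, MpR2R3-MYB14 rose 7.30-fold and MpNAC7 rose 5.57-fold.

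Genes of dividing cells, here histones and cell-cycle genes active in the apical notch, fell as a list. Of 39 members 33 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 2.22e-07, and adjusted p = 0.559 with an estimated correlation). The histone gene MpH3.1d fell from 13.4 ± 1.10 to 4.25 ± 1.37 CPM (SD, n = 3), and MpH4b fell by 1.51 on the log2 scale. The 3 tested genes of the Calvin cycle and chlorophyll synthesis fell, over all genes and adjusted over the list alone (camera adjusted p = 0.0426, and adjusted p = 0.559 with an estimated correlation). Among them were MpCHLD, a subunit of magnesium chelatase, which fell by 1.06 on the log2 scale, and MpRBCS, the small subunit of Rubisco, which fell by 0.84. Of 80 genes of cell wall remodelling 36 fell and 18 rose, also when adjusted over the list alone (camera adjusted p = 0.319). MpGH16.30 fell by 2.83 and MpGH16.7 rose by 3.38 ± 0.17 on the log2 scale (SE).

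The remaining lists, most of them with genes that moved both ways, did not pass camera. Of 84 cytochrome P450 genes 26 rose and 26 fell (26 and 27 adjusted over the list alone, camera adjusted p = 0.637). MpCYP815A1 rose 43.2-fold and MpCYP813B1 fell from 15.8 ± 1.18 to 1.17 ± 0.411 CPM (SD, n = 3). Of 39 pathogenesis-related and chitinase genes 12 rose and 4 fell (11 and 4 adjusted over the list alone, adjusted p = 0.316), with MpPR15e higher at 3.24 ± 1.20 CPM (SD, n = 3), from a level near what a count of 0 allows. Of 36 cupin genes 5 rose and 10 fell (4 and 9 adjusted over the list alone, adjusted p = 0.319), and MpCupin84 fell by 3.20 on the log2 scale. Of 50 genes of glutathione S-transferases and redox enzymes 20 rose and 15 fell in both counts (adjusted p = 0.361), and MpGST38 rose by 4.32 ± 0.52 on the log2 scale (SE). Of 29 auxin genes 7 rose and 9 fell (8 and 9 adjusted over the list alone, adjusted p = 0.711). MpGH3A, an amido synthetase gene, rose from 59.2 ± 4.00 to 635 ± 105 CPM (SD, n = 3), and its relative MpGH3B fell by 1.20 on the log2 scale. Of 67 genes of abscisic acid and desiccation 9 rose and 7 fell (9 and 4 adjusted over the list alone, adjusted p = 0.416, in the upward direction, whereas the median log2 fold change was -0.24), and the dehydrin gene MpDHN2 rose by 2.86 ± 0.21 (SE). Of 31 genes of 2-oxoglutarate-dependent oxygenases 6 rose and 14 fell (6 and 15 adjusted over the list alone, adjusted p = 0.319). Of 23 ion transport genes 7 rose and 6 fell (7 and 7 adjusted over the list alone, adjusted p = 0.694), and the proton pump gene MpHA14 fell by 1.62 on the log2 scale. Of 5 heat shock protein genes 3 rose and 1 fell (adjusted p = 0.119), with MpHSP90-2 higher by 1.58 ± 0.07, and of 5 calcium signalling genes 1 rose and 2 fell (adjusted p = 0.633). Of 9 terpene synthesis genes 3 rose and 1 fell (adjusted p = 0.62), and MpFTPSL8 rose 5.79-fold. These 3 lists had the same counts adjusted over the list alone. MpTPS6, which was not in the terpene list, fell by 4.90 on the log2 scale. This change was not called by limma-voom (adjusted p = 0.0595, against 6.21e-09 to 0.0595 over all alternatives). Of 40 V chromosome genes 1 rose and 8 fell (1 and 5 adjusted over the list alone, adjusted p = 0.448), and of 6 genes of reproductive cells 1 fell in both counts (adjusted p = 0.485).

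**Figure D1:**
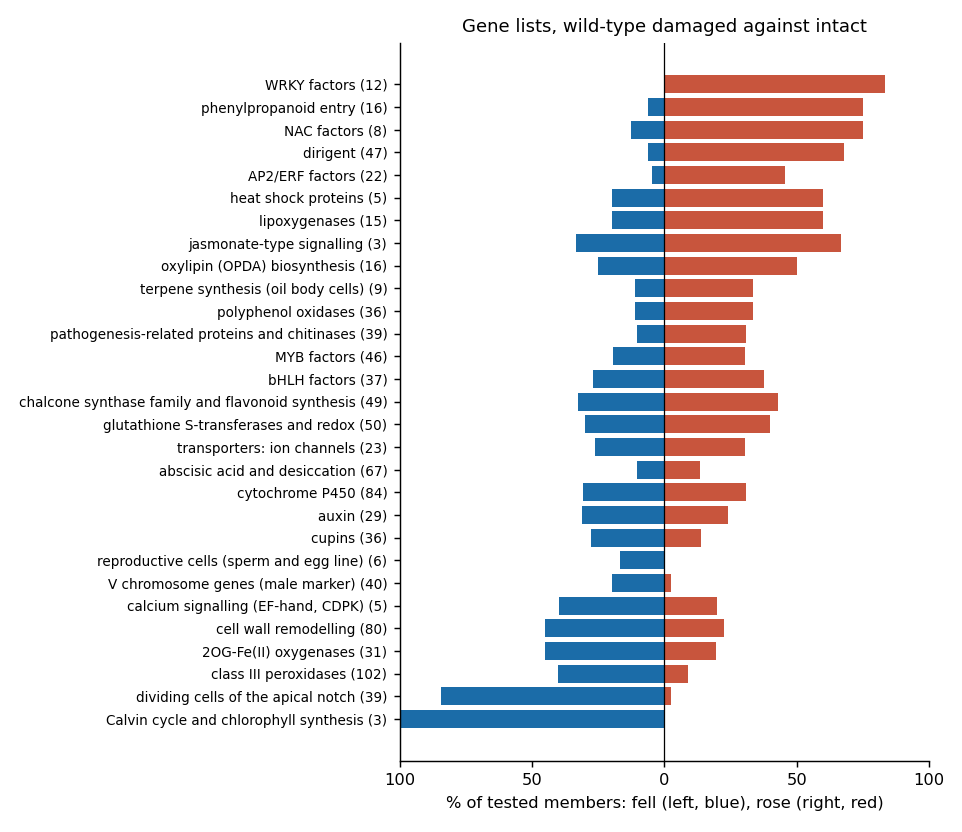
Percent of the tested members of each gene list that fell (blue, to the left) or rose (red, to the right) at an adjusted p under 0.05 in damaged against intact wild-type thallus, n = 3 libraries per group, with the number of tested members in brackets. Of the dirigent genes 32 of 47 rose, and of the genes of dividing cells 33 of 39 fell.

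The same comparison in Mpglr-9 asked whether the local response needs MpGLR. Crushing was followed by a change of 7369 genes in the mutant, 3712 higher and 3657 lower. The same direction was called in both genotypes for 3306 higher and 3191 lower genes, where independent lists of these sizes would share 1029.7 and 1016.3, and 0 genes were called in opposite directions. The 2 responses shared no library, but libraries of the same number were correlated between the genotypes in intact plants and in damaged lobes. Such libraries may share a batch, so the responses need not be independent. Across all 13450 genes, which are not independent replicates, the log2 fold changes of both genotypes correlated with Pearson r = 0.931 and Spearman rho = 0.905. Over the genes called in the wild type the slope of the mutant on the wild-type change was 0.969, and over the genes called in the mutant the slope of the wild-type on the mutant change was 0.918. With genes chosen without a given damaged wild-type library and measured in that library, the slope of the mutant on the wild type was 0.924, 1.046 and 1.155. Here the wild-type change was log2 CPM (prior count 2) minus the mean of the intact libraries, which also served in the choice. The mutant change was the fold change of the model, so the 2 measures differ and these slopes are only approximate.

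The genes named here from the wound response were called in the same direction in the mutant. MpLOX2 rose by 3.56 ± 0.11 (SE, n = 3), MpJAZ by 2.42 ± 0.10 and MpERF15 by 3.92 ± 0.26 on the log2 scale, while MpH3.1d fell by 1.36 and MpCYP813B1 fell by 3.54. MpDIR39 rose by 9.23 ± 0.52, against 6.53 ± 0.42 in the wild type, from 0.743 ± 0.552 CPM in intact mutant plants (SD, n = 3). MpPPO31 rose to 124.5 ± 49.9 CPM (SD, n = 3) from a level under the 0.108 to 0.112 CPM that a count of 0 allows in intact mutant plants, so no fold is given. Neither gene passed the interaction test (adjusted p = 1 for both). Dirigent genes rose in 31 and fell in 2 of 47 cases, WRKY genes rose in 11 of 12, phenylpropanoid entry genes rose in 11 and fell in 2 of 16, lipoxygenase genes rose in 7 and fell in 3 of 15, class III peroxidase genes rose in 11 and fell in 47 of 102, and genes of dividing cells rose in 1 and fell in 32 of 39. Adjusted over the list alone these counts were the same, except for 9 and 3 lipoxygenase genes. The 6 lists passed camera in the mutant (largest adjusted p = 0.0272) but not with an estimated correlation (adjusted p = 0.559 for each). The list of the Calvin cycle and chlorophyll synthesis, which passed in the wild type, did not pass in the mutant. Its genes MpCHLD, MpCHLI1/2-like and MpRBCS fell there by 1.04, 1.00 and 0.67 on the log2 scale.

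The interaction, the direct test of a difference between the genotypes in the local response, called 0 genes with edgeR, 0 with DESeq2 and 0 with limma-voom. At an unadjusted p under 0.05 it held 335 genes, 2.5% of those tested. Without any difference a share of 0.05 would fall there, so the interaction test may be conservative. With the replicate block it held 456 genes at that p and called 0. That block gives each replicate number 1 effect common to all 6 groups. Spread that libraries of the same number share in a single condition therefore stayed in the error. No fit that pairs the genotypes inside each condition was made. Of the 8341 genes called in either genotype, 87.8% had a 95% interval of the interaction within 1 of 0 on the log2 scale. Among the 1873 with a log2 change of at least 1 in either genotype the share was 54.6%, so differences of more than 2-fold were not excluded for the other strongly responding genes. Among the genes with the smallest interaction p were MpDIR5, with a log2 difference of 1.01 ± 0.24 (SE, adjusted p = 1), and MpPR9b, with a difference of -3.75 ± 1.15 (SE, adjusted p = 1), at few counts. Without wild-type intact replicate 1 the test called 1 gene, MpDIR5, at 1.23 (adjusted p = 0.0396). Adjusted over the list alone 1 dirigent gene was higher in the interaction. Pathogenesis-related genes (down, adjusted p = 0.0211) and genes of dividing cells (up, adjusted p = 0.00266) passed camera in the interaction without any called member, and neither held with an estimated correlation (adjusted p = 0.968 for both).

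**Figure D2:**
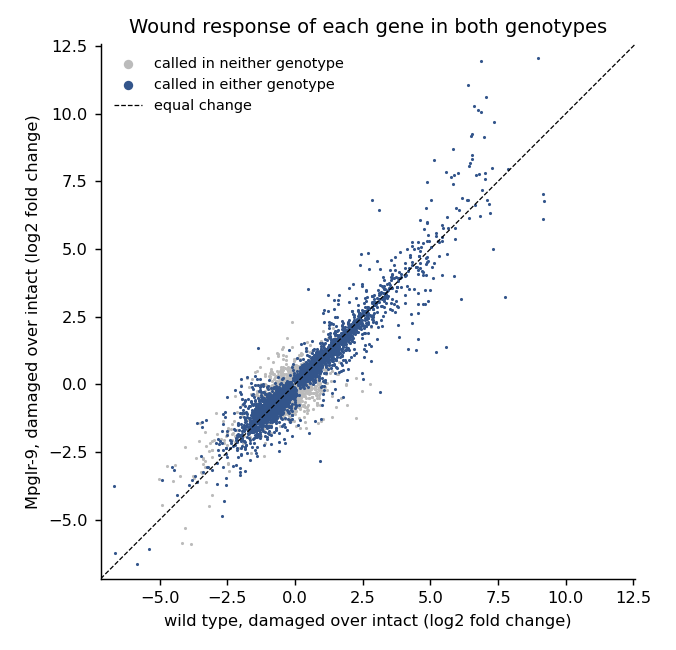
Each point is 1 of the 13450 tested genes, with its log2 fold change from intact to damaged in the wild type on the horizontal axis and in Mpglr-9 on the vertical axis, from 3 libraries per group. Genes called in either genotype are blue, the dashed line marks equal change, and the correlation across genes is 0.931.

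The untouched lobes of wounded plants were compared with intact plants to measure a systemic response. In the wild type edgeR called 0 genes, with 353 genes (2.6%) at an unadjusted p under 0.05. Without any difference a share of 0.05 would fall there, so this test may be conservative. With the replicate block 524 genes fell there and 1 was called. For the wild type limma-voom called 0, and DESeq2 called 6 genes, all lower, among them the dirigent genes MpDIR39 and MpDIR5. In the mutant edgeR, DESeq2 and limma-voom called 0 genes, with 810 (6.0%) at an unadjusted p under 0.05. Adjusted over the list alone 2 dirigent genes were lower in the wild type, and 1 gene of the chalcone synthase family and 1 AP2/ERF gene were lower in the mutant. Without wild-type intact replicate 1 the wild-type comparison called 3 genes, all lower, and without any of the libraries numbered 3 it called 4, all higher. The systemic libraries carried little of the local response. As a share of the damaged response of the other genotype, the damaged libraries scored 94.4 ± 10.2% in the wild type and 97.6 ± 10.3% in the mutant (SD, n = 3), and the systemic libraries scored -4.6 ± 1.0% and -0.6 ± 3.1% (SD, n = 3). Intact libraries ranged from -4.7 to 6.3% in the wild type and from -4.0 to 7.4% in the mutant, and the systemic scores lay within these ranges except for wild-type systemic replicate 2 at -5.6%.

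With no systemic call, the overlap of damaged and systemic calls was 0 in both genotypes. In 10 simulations of an unchanged group against the shared intact controls it was also 0. The log2 fold changes of the damaged and systemic comparisons share their intact libraries. Their covariance was -0.023 in the wild type and 0.024 in the mutant, against 0.002 and 0 in the simulations. The simulated group was drawn around the observed intact means, so chance error of the shared intact libraries did not enter its change. An overlap and a covariance near 0 were thereby built in, and the simulations do not show what shared controls alone give. The interaction in systemic lobes called 0 genes with edgeR, DESeq2 and limma-voom. In edgeR 356 genes (2.6%) had an unadjusted p under 0.05, fewer than the share of 0.05 that no difference would give. Among the genes with the smallest p, MpPKS/CHS-like1 had a log2 difference of -0.38 ± 0.10 (SE, adjusted p = 1). In the mutant, pathogenesis-related genes (adjusted p = 0.0317) and auxin genes (adjusted p = 0.0375) were lower in camera without a called member, which did not hold with an estimated correlation (adjusted p = 0.667 and adjusted p = 0.401).

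**Figure D3:**
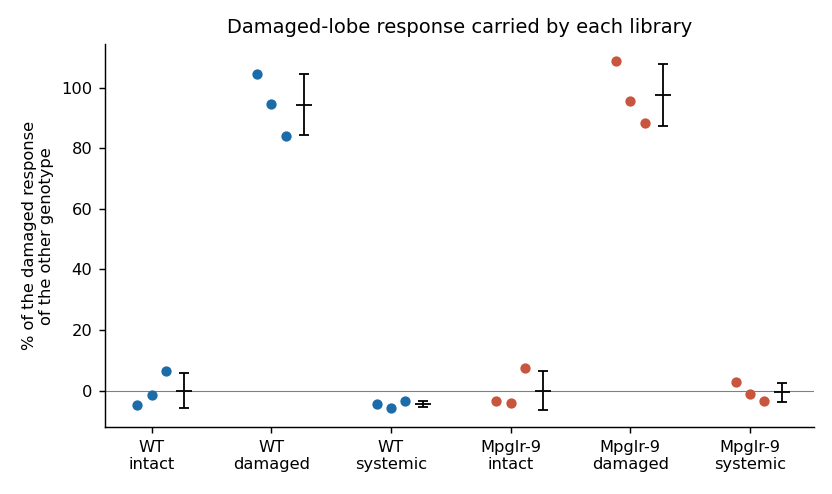
Share of the damaged response of the other genotype carried by each library, in percent, with wild-type libraries in blue and Mpglr-9 libraries in red; each point is 1 library and the black bars give mean and SD of 3. Damaged libraries lie between 84.2 and 108.7%, and intact and systemic libraries between -5.6 and 7.4%.

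Mutant and wild type were also compared within each condition. In intact plants 3 genes were called, all higher in the mutant. Mp7g01940 was 19.5-fold higher (log2 fold change 4.29 ± 0.06, SE, n = 3, adjusted p = 3.12e-18), Mp3g21250 was 15.8-fold higher (3.98 ± 0.12) and MpVg00700, a gene of the V chromosome that marks male plants, was 1.69-fold higher (0.75 ± 0.10). None of these genes has a symbol. In damaged lobes the same 3 genes were higher, at 17.5-fold, 11.6-fold and 1.71-fold. There 1 further gene, Mp4g19430, was higher by 2.19 ± 0.34 on the log2 scale, at 1.83 ± 0.129 against 0.403 ± 0.162 CPM (SD, n = 3). In intact plants Mp4g19430 was not called, yet its libraries held 1.5 to 1.85 CPM in the mutant and 0.563 to 0.747 CPM in the wild type. In systemic lobes its values overlapped between the genotypes. In systemic lobes 7 genes were called, all higher in the mutant, among them Mp7g01940 at 20.3-fold, Mp3g21250 at 17.4-fold and MpVg00700 at 1.76-fold. Mp4g19400, close to Mp4g19430 in locus number, was also among the 7. Over the 3 conditions it held 1.55 to 3.01 CPM in the mutant and 0 to 0.525 CPM (0 to 15 counts) in the wild type. The main fit did not call Mp4g19400 in intact plants or damaged lobes, whereas DESeq2 called it in all 3 conditions. Across conditions Mp7g01940 ranged from 269 to 335 CPM in the 9 wild-type libraries and from 4750 to 6310 CPM in the 9 mutant libraries. Mp3g21250 ranged from 53.6 to 85.4 CPM and from 774 to 1140 CPM.

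Fitted on the groups compared alone, MpVg00700 was not called in intact plants (log2 fold change 0.75, adjusted p = 0.126, against 6.33e-09 to 0.126 over all alternatives) or damaged lobes (0.77, adjusted p = 0.271, against 1.69e-08 to 0.271). Mp4g19430, chosen after its values were seen, was not called on the groups compared alone (log2 fold change 2.19, adjusted p = 0.336) or without the libraries numbered 3 (1.84, adjusted p = 0.119). It was also not called in 5 of the 6 fits that left out 1 damaged library (1.89 to 2.31, adjusted p 0.0538 to 0.0855). The counts beyond the first 2 genes and their directions depended on the method. In damaged lobes the fit with a replicate block called 9 genes (1 lower in the mutant), DESeq2 28 (10 lower), the fit on the groups compared alone 2 (0 lower), the fit without the libraries numbered 3 called 14 (6 lower), and leaving out wild-type damaged replicate 3 gave 11 (6 lower). In systemic lobes DESeq2 called 31 genes (9 lower) and the fit on the groups compared alone 28 (4 lower). Leaving out wild-type systemic replicate 1, 2 or 3 gave 3, 3 and 4 genes (0, 0 and 1 lower), and leaving out mutant systemic replicate 2 or 3 gave 4 each (1 and 0 lower). In intact plants DESeq2 called 6 genes (1 lower). Dirigent genes (down, adjusted p = 0.0289) and pathogenesis-related genes (up, adjusted p = 0.0488) passed camera in intact plants, and genes of dividing cells (adjusted p = 0.0023), cell wall remodelling (adjusted p = 0.0117), abscisic acid and desiccation (adjusted p = 0.0117), auxin (adjusted p = 0.017) and AP2/ERF factors (adjusted p = 0.0421) were lower in systemic lobes of the mutant, all without a called member. None held with an estimated correlation, where the smallest adjusted p of these lists was 0.954 in intact plants and 0.418 in systemic lobes. Adjusted over the list alone 1 cell wall gene was lower in intact plants and 1 in systemic lobes. In damaged lobes 2 lipoxygenase genes, 2 genes of the chalcone synthase family and 1 cytochrome P450 gene were then higher, and 1 bHLH and 1 ion transport gene lower. Of the 40 V chromosome genes 1 rose in each condition (2 higher in intact plants, 3 higher and 2 lower in damaged lobes and 3 higher and 1 lower in systemic lobes when adjusted over the list alone).

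**Figure D4:**
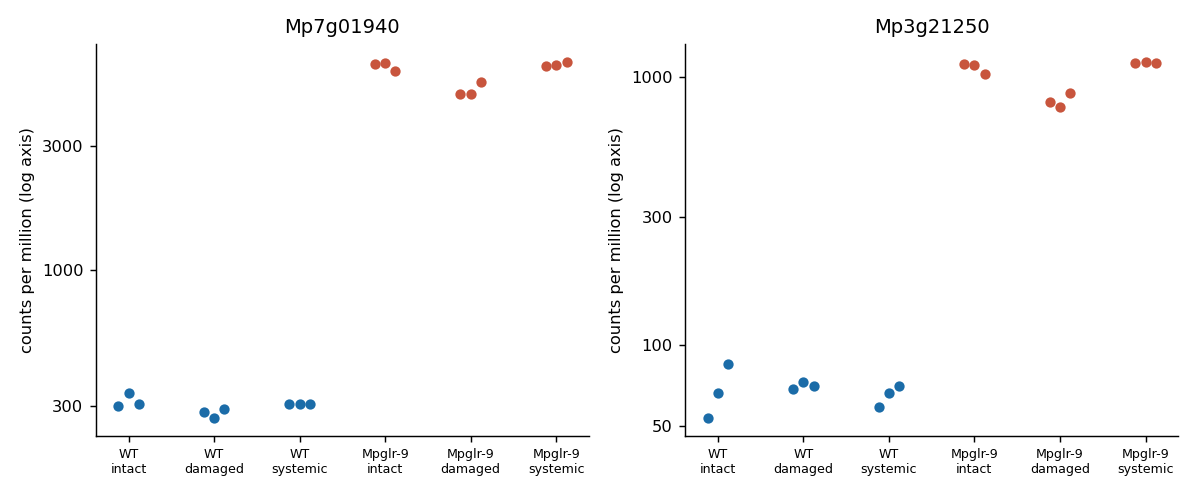
CPM of Mp7g01940 (left) and Mp3g21250 (right) on a log axis in each library, wild type in blue and Mpglr-9 in red, with 3 libraries per group. For both genes all 9 mutant libraries lie above all 9 wild-type libraries.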

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

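Leaving out the libraries numbered 3 was chosen after the data were examined, and the other alternatives were planned. Of 210 recomputed summary values 170 stayed within the limits set for calling them unchanged and 40 moved. The damaged responses kept between 86.6 and 99.5% of their wild-type calls and between 85.6 and 99.6% of their mutant calls across tools, scalings, filters and left-out libraries. A minimum log2 fold change of 1 left 1635 wild-type and 1548 mutant calls, by construction. For systemic against intact wild-type thallus the 0 calls became 6 with DESeq2, 1 with the replicate block and 4 without the libraries numbered 3. Mutant against wild type gave 6 calls with DESeq2 in intact plants. In damaged lobes it gave 28 with DESeq2, 9 with the replicate block, 2 on the groups compared alone and 14 without the libraries numbered 3. In systemic lobes it gave 31 with DESeq2, 16 with the replicate block, 28 on the groups compared alone, 12 without the libraries numbered 3, and 4 both at an adjusted p under 0.01 and with a minimum log2 fold change of 1. The interaction in systemic lobes called 1 gene without the libraries numbered 3. Leaving out 1 library at a time gave 6730 to 7431 calls for the wild-type and 6418 to 7177 for the mutant damaged response, 0 to 3 for the wild-type and 0 for the mutant systemic response, 3 for mutant against wild type in intact plants, 3 to 11 in damaged and 3 to 6 in systemic lobes, 0 to 1 for the interaction in damaged lobes and 0 for that in systemic lobes. Of the gene lists, 7 passed camera in the wild-type and 6 in the mutant damaged response, against 0 and 0 with an estimated correlation. With fry, which tests against no change, 24 and 22 passed. The lists that passed in the mutant systemic response (2), in mutant against wild type in intact plants (2) and systemic lobes (5) and in the interaction in damaged lobes (2) numbered 0 with an estimated correlation and 0 with fry. With the replicate block in camera 1 list passed in each systemic response and 2 in the interaction in systemic lobes. The block moved no other count beyond 1.5-fold. Except for the minimum fold change and the stricter threshold, the cause was not tested. Of 1151 recomputed values of named genes 1137 kept their direction and side of the threshold, 13 were no longer called, 1 was newly called and 0 reversed. Mp4g19400 was not among these genes. Depth limits genes near the limit of 0.098 to 0.173 CPM that a count of 0 allows.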

Other observations

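The tests of a mislabelled library, of a changed wound response, of a weaker copy of the damaged response of chance gene order and of stretches of neighbouring pairs were chosen after the result was seen, as were the comparison of the libraries numbered 3, the screen of symbol families and the stretch on chromosome 5. Several genes that rose at least 2-fold in damaged wild-type lobes were neighbours in the order of locus numbers. On chromosome 4 the phenylalanine ammonia-lyase and chalcone synthase family genes MpPAL7, MpPKS/CHS11, MpPAL6, MpPKS/CHS12, MpPAL-like2 and MpPKS/CHS13 formed a run of 7 risen genes with Mp4g14170, with a median log2 fold change of 2.16. On chromosome 5 the dirigent genes MpDIR65, MpDIR61, MpDIR42, MpDIR41 and MpDIR39 and the polyphenol oxidase gene MpPPO28 formed a run of 6, with a median of 6.52. On chromosome 2 MpBHLH2, MpBHLH3 and MpBHLH4 lay in a run of 7, with a median of 3.04. On chromosome 3 MpPIWIb and MpPIWIa, neighbouring genes of Argonaute-type proteins, rose by 5.04 and 3.19 on the log2 scale. In all, 9 runs held at least 5 neighbouring risen genes. These genes were chosen after their values were seen. Of 60 symbol families with at least 5 members outside the fixed lists, 0 passed camera in either damaged response, and the smallest adjusted p with an estimated correlation was 0.78 in the wild type and 0.801 in the mutant.

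The libraries numbered 3 were compared with those numbered 1 and 2 over all groups together, and no group was tested alone. In damaged lobes the libraries were rather graded by number. On the first principal component those numbered 1, 2 and 3 lay at 81.1, 68.3 and 56.4 in the wild type and at 79, 66 and 56.8 in the mutant. With the group means in the model, 1266 of 13450 genes differed, 674 higher and 592 lower in the libraries numbered 3, and 130 and 47 of them by at least 2-fold. Of 67 genes of abscisic acid and desiccation 27 were higher and 1 lower (camera adjusted p = 1.48e-09, and adjusted p = 0.392 with an estimated correlation). Of 102 class III peroxidase genes 31 were lower and 0 higher (adjusted p = 5.43e-08, and adjusted p = 0.172 with an estimated correlation), and of 36 polyphenol oxidase genes 13 were lower and 2 higher (adjusted p = 8.82e-05, and adjusted p = 0.172 with an estimated correlation). The labels give no day or batch for these libraries. In systemic lobes 11 neighbouring loci from Mp5g04540 to Mp5g04660 had log2 values of 1.45 to 2.66 for mutant against wild type, beside -0.8 to 1.41 in intact plants and -0.15 to 0.95 in damaged lobes. In systemic lobes none was called (smallest adjusted p = 0.079), whereas 9 were called on the groups compared alone, 7 by DESeq2 and 3 with the replicate block.

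Mp7g01940 and Mp3g21250 were over 10-fold higher in the mutant in all 3 conditions. A change of the surrounding chromosome segment is argued against by the 10 flanking genes, whose median absolute log2 fold change of 0.051 and 0.052 reached at most the percentile 54.9 of random stretches. Genes over 10-fold apart in 2 conditions were also measured in the libraries of the third, and each such choice gave these 2 genes alone. The lowest mutant library there was at least 10.6 times the highest wild-type library, so no single library lay on the side of the other genotype. The pattern had been seen in all 3 conditions before, so this is no separate test of a library exchanged between the genotypes. Labels exchanged between whole genotypes, or between conditions within a genotype, would not show in these values. The difference was present without wounding, since in intact plants genes chosen in wounded plants differed by at least 15.8-fold (log2 3.98 ± 0.19, SE). A difference in all 3 conditions already defined the pattern, so this outcome was known beforehand. It is no separate test of a changed wound response. Smaller changes with wounding stay open, with interaction values of -0.15 ± 0.08 and -0.45 ± 0.16 in damaged and 0.06 ± 0.08 and 0.14 ± 0.16 in systemic lobes (SE, adjusted p = 1 for all 4). A difference between the 2 lines may underlie both genes, and whether it follows from the loss of MpGLR or from another difference was not tested, since 1 mutant line was sequenced.

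No gene was called in untouched lobes of wounded plants with edgeR (353 genes at an unadjusted p under 0.05 in the wild type and 810 in the mutant), against 6 and 0 with DESeq2 and 0 and 0 with limma-voom. The 95% intervals were narrower than 1 log2 unit to either side for 93.5% of genes in the wild type and 93.7% in the mutant. At an interval just under this width a 2-fold change has an unadjusted p near 0.05. Adjusted over 13450 genes it would not be called, so these are not shares of genes with a callable 2-fold change. The median SE was 0.095 in both systemic comparisons. A spread too wide for 2-fold changes is argued against for genes near or below that SE, and stays open for genes of wider spread. Among genes changed at least 2-fold in damaged lobes of the other genotype, the systemic interval excluded 0.5 times that log2 change for 81.8% (1266 of 1548) in the wild type and 80.7% (1320 of 1635) in the mutant, so a change of that size stays open for the others. A weaker copy of the damaged response of 10% or more is argued against by the scores, of which the highest systemic library reached 2.8%. Since intact libraries reached 7.4%, a copy of a few percent may have gone unseen. A response at another time than 4 h, or in few genes, stays open and was not tested.

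Neighbouring genes rose together more often than a random order gave. Of 13363 neighbouring pairs 231 had both genes risen at least 2-fold, against 73.9 on average and 59 to 90 (95% range) in 1000 shuffles within chromosomes, which argues against a chance order. Tandem copies of 1 family that share reads or promoters stay open. Of 414 pairs of named genes with different family symbols 15 rose together, against 5.2 on average (1 to 10), but pairs in 1 stretch are not independent, and 6 of them lay in 1 stretch of MpPAL and MpPKS/CHS genes. Counted as stretches there were 9, against 5 on average (1 to 9). No biological explanation was tested.

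Refits with the libraries of the compared groups regrouped gave the following. A comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. The real split and the highest other gave 6548 and 0 calls for the wild-type and 6779 and 0 for the mutant damaged response, where 1 split gave as many, the real one included. For the systemic responses they gave 0 and 2 calls in the wild type and 0 and 0 in the mutant. No split has fewer than 0 calls, so all 10 gave as many by construction, which tests nothing. For mutant against wild type they gave 2 and 19 in intact plants (4 splits with as many), 2 and 185 in damaged lobes (2 splits) and 28 and 25 in systemic lobes (1 split). The splits with 19 and 185 calls set libraries 1 and 2 of the wild type and 1 of the mutant against the rest, which points to structure among the numbered libraries. In these 2 comparisons the numbers pair the libraries. Of the splits that part all 3 pairs only the real one called a gene, and the others part 1 pair. The fits with a replicate block called 3 and 9 genes there. For the interactions 40 splits were drawn, and with 0 calls in the real one all 40 gave as many by construction, which tests nothing either. The highest others gave 232 calls in damaged and 129 in systemic lobes, which points to structure among the libraries that was not traced.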
